A study of Homo sapiens with 24 samples.

How the data were processed

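Gene expression was measured by 3' mRNA sequencing (QuantSeq, a kit that reads the 3' end of polyadenylated transcripts) in 2 human fibroblast lines, BJ from skin and HFL1 from fetal lung. Each line was studied in 2 models of premature senescence, sustained inhibition of the proteasome with bortezomib and oxidative stress with hydrogen peroxide (H2O2), and each model had its own untreated control group. Per the labels, bortezomib was given for 10 days to BJ and for 9 days to HFL1, H2O2-treated cells recovered for 72 hours, and 500 ng of total RNA entered each library. This gave 8 groups of 3 libraries, 24 in all. The labels call those of a group biological replicates but do not say what set them apart (culture, passage or day). So gene p-values measure only library spread. List and Fisher tests compare genes.

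The authors aligned the reads with STAR to GRCh38; versions and settings were not stated. The deposited tables hold counts per 3' region (162106 regions) and counts per gene (60527 genes), together with the GC content of each gene in percent per the file headers. The gene table is named as normalized, but each of its 1452648 values equals the sum of the gene's region counts (0 differed), so both tables were read as raw counts. Gene sums were used here; differences between 3' regions of a gene were not analysed here. Gene positions (GRCh38) and symbols are those of the files. None of the 13 mitochondrially encoded mRNAs of a prepared list is among the genes of the tables, so that list was not analysed here.

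Totals per library ran from 3070865 to 6553742 counts. A group at 0 counts was given a floor of 3 counts summed over its 3 libraries, which is 0.189 to 0.297 CPM (counts scaled to a common library size) by group. A fold against such a group is a lower bound. A gene with 1 to 3 counts in a group is given as the ratio of scaled counts with an exact (Clopper-Pearson) 95% interval. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

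Genes were kept by the filterByExpr function of edgeR 4.0.16 over the 8 groups (16160 genes), scaled by TMM and fitted in 1 quasi-likelihood model with a mean per group (glmQLFit with the robust option, glmQLFTest, 16 residual degrees of freedom, R 4.3.3). No replicate block was used. Adjusted p-values are Benjamini-Hochberg values over all genes tested, all tests were two-sided, and a gene was called at an adjusted p below 0.05. Rose, fell and changed are used for called genes and for called lists. Fold changes are log2 with their standard error (SE); levels are TMM-scaled CPM as mean ± SD of 3 libraries. Each treated group was compared with its own controls, giving 4 comparisons. Interaction contrasts in the same model compared the effects of an inducer between lines (HFL1 minus BJ) and the effects of both inducers within a line (bortezomib minus H2O2). The control groups of the 2 arms of a line were also compared with each other. Counts expected for overlapping lists assume independence per direction.

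The model was tested on simulated data of the same layout (15753 genes, 100 genes changed at each fold in each comparison). It recovered 27%, 34%, 24% and 22% of 2-fold changes and 75%, 72%, 75% and 78% of 4-fold changes in BJ with bortezomib, BJ with H2O2, HFL1 with bortezomib and HFL1 with H2O2. Unchanged genes called numbered 1 in the first comparison and 5 in each other one.

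There were 30 gene lists (812 entries, 797 matched), fixed before the data were examined, as were the main test, its alternatives and the rule for named genes. They were mitosis and G2/M, DNA replication, replication-dependent histone, p53 target, inflammatory secreted factor, secreted protease and growth factor, proteasome subunit, heat shock protein and co-chaperone, ER chaperone and IRE1/ATF6 target, ATF4 target and amino acid response, NRF2 target and antioxidant, metallothionein, autophagy and ubiquitin adaptor, lysosome, interferon-stimulated, fibrillar collagen and matrix, contractile and myofibroblast, cholesterol synthesis, cytosolic ribosomal protein, nuclear-encoded oxidative phosphorylation, mitochondrially encoded, glycolysis and hypoxia, and immediate-early genes, chromatin and nuclear envelope genes known to fall in senescence, and published transcripts raised across senescence models. Markers of epithelium and keratinocytes, endothelium, leukocytes, smooth muscle and pericytes, and fibroblasts completed them. Lists with at least 3 tested genes (29) were tested with camera (limma 3.58.1, preset correlation 0.01 between genes of a list), with Benjamini-Hochberg adjustment over the 116 tests of the 4 comparisons. Each test was repeated with a correlation estimated per list. Members called over all genes tested are set beside those called with adjustment over the list alone (list-wise). In 11 of the 116 tests the median, the mean and the direction of the test differed in sign. How many of these were called was not counted. The fry rotation test, which tests a list against no change, was run as an alternative and is left out of the ranges of adjusted p given for lists.

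Named genes followed a rule. For each comparison they were the 6 largest rises and 6 largest falls among called genes with a symbol, a mean of at least 10 CPM over the 6 libraries and all 3 libraries of one group above all 3 of the other (chance gives 10% of genes such a separation), a fixed panel of 24 genes, and up to 4 members of each list with the smallest adjusted p. For genes shared by all 4 comparisons they were the 10 rises and 10 falls with the largest smallest change and a mean of at least 10 CPM over the 24 libraries, and for each interaction the 5 largest called differences of each sign with a mean of at least 10 CPM over its 12 libraries. Clone names were left out of all these rankings, so genes of lower level or without a symbol can exceed those named. Genes of the Y chromosome and XIST were never named.

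Reads were counted without regard to strand: in 5 of 5 pairs of regions on opposite strands the counts lay within 5% of each other. Of 12384 genes with at least 480 counts, 3253 had over 50% of their reads in regions that overlapped another gene, and 835 had a gene of near-identical counts. A named gene of either kind is given as sharing reads, and its identity is uncertain. Some single genes are not reported here.

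Replicate numbers were checked for pairing by correlating deviations from group means across 9804 genes between a treated and a control library of the same number. In BJ with bortezomib the correlations were 0.271, 0.369 and 0.108, so values with a replicate block are given for that comparison where they change a call. Across-gene correlations describe genes, which are not independent replicates.

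The alternatives fixed beforehand were size factors of DESeq2 (RLE) and library size in place of TMM, no filter on low counts, a filter at a mean CPM, DESeq2 1.42.0, only the libraries of the comparison, a replicate block, and leaving out each library in turn. A planned limma fit on the table named as normalized was replaced by limma-trend on TMM-scaled log2 CPM, since that table holds counts. Alternatives chosen after the data were seen were limma-trend, an offset for GC content (lowess span 0.2), genes sharing few reads, and fits without the libraries that stood apart from their groups. Other splits of the libraries (10 for 6 libraries, 100 drawn for more) were fitted in the same way. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.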

Results

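The 24 libraries came from BJ skin and HFL1 lung fibroblasts, both established human lines. Cells were made senescent with bortezomib, a proteasome inhibitor, or H2O2, an oxidant. Each treated group had its own untreated controls of proliferating cells. Each of the 8 groups had 3 libraries, of 3070865 to 6553742 counts each. The first 3 principal components held 32.6%, 24.2% and 17.7% of the variance of log2 CPM. Libraries of a group correlated across genes at 0.947 or more, except replicate 2 of the H2O2-treated BJ group (library T2), which correlated at 0.770 and 0.783 with the others of its group. That library also had the highest mean GC content of its reads, 50.32%, and the largest share of counts in nuclear copies of mitochondrial sequence, 2.87%. Replicate 2 of the BJ controls of the bortezomib arm had 15.91% of its counts in genes at ribosomal RNA loci.

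**Figure D1:**
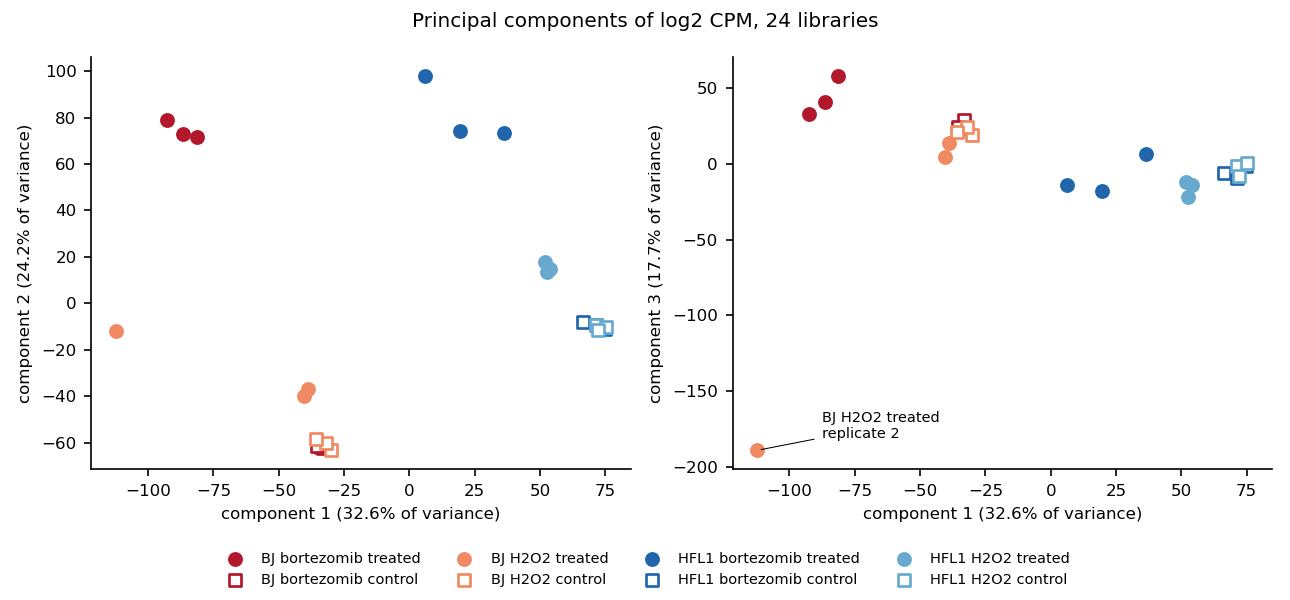
Principal components of log2 CPM for the 24 libraries; each point is a library, filled circles are treated and open squares untreated, and the axes give the share of variance (32.6%, 24.2% and 17.7%). Library T2 lies away from its group on component 3.

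To determine which genes responded to proteasome inhibition in skin fibroblasts, bortezomib-treated BJ cells were compared with untreated BJ cells. Genes of the proteasome, of protein folding and of autophagy rose, while genes of cell division, interferon response and chromatin fell. Of 34 proteasome subunit genes, 32 rose and 0 fell (33 and 0 list-wise, median log2 fold change 1.45, adjusted p = 7.22e-16). PSMD2, a subunit of the regulatory particle, had a log2 fold change of 2.43 (SE 0.18) and PSMC4, an ATPase of the same particle, of 2.40 (SE 0.23). Of 31 genes of heat shock proteins and co-chaperones, 26 rose and 1 fell (27 and 1 list-wise, median 1.74, adjusted p = 7.12e-14). HSPA1A, which encodes an inducible cytosolic chaperone (ENSG00000204389, GRCh38 chromosome 6, 31815543 to 31817946), rose from 74.6 ± 4.71 to 4520 ± 342 CPM (SD, n = 3; log2 fold change 5.92, SE 0.63, adjusted p = 2.45e-07). HSP90AA1, a stress-inducible form of a major chaperone, rose by 3.64 (SE 0.25). Of 28 autophagy and ubiquitin adaptor genes, 14 rose and 3 fell (15 and 4 list-wise, median 0.59, adjusted p = 0.00102). SQSTM1, an autophagy receptor that shares reads with MRNIP, rose from 764 ± 62.5 to 5130 ± 332 CPM. Without library T2, which enters the shared estimate of spread, 20 autophagy genes rose and 6 fell. These 3 list calls held with an estimated correlation.

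Antioxidant and lysosome genes moved in both directions in these cells. Of 30 NRF2 target and antioxidant genes, 15 rose and 6 fell (15 and 7 list-wise, median 0.80, adjusted p = 0.00972, 0.0781 with an estimated correlation). HMOX1, which encodes the heme-degrading enzyme heme oxygenase, rose from 21.8 ± 5.99 to 311 ± 39.6 CPM (log2 fold change 3.84, SE 0.36, adjusted p = 5.59e-08). NQO1, a quinone reductase gene and a standard NRF2 target that shares reads with another gene, fell by 2.59 (SE 0.19, adjusted p = 2.72e-09). Of 32 lysosome genes, 13 rose and 4 fell (the same counts list-wise, median 0.51, adjusted p = 0.0068, 0.099 with an estimated correlation), and without library T2, 20 rose and 7 fell. GLA, an alpha-galactosidase gene, rose by 4.40 (SE 0.40), while GAA, an alpha-glucosidase gene, fell by 2.26 (SE 0.28).

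Genes of proliferation fell in bortezomib-treated BJ cells. Of 33 mitosis and G2/M genes, 0 rose and 25 fell (0 and 26 list-wise, median -2.42, and -2.29 with the 6 members that had 0 counts in a group at their bound; adjusted p = 2.11e-10). MKI67, a marker of cycling cells (ENSG00000148773, GRCh38 chromosome 10, 128096659 to 128126423), fell from 138 counts to 1 count over 3 libraries, a ratio of 112 (95% interval 19.8 to 4460). Of 36 DNA replication genes, 3 rose and 25 fell, also list-wise (median -1.43, adjusted p = 6.74e-06). RRM2, a ribonucleotide reductase subunit, fell by 3.74 (SE 0.36). Of 25 chromatin and nuclear envelope genes known to fall in senescence, 0 rose and 18 fell (1 and 18 list-wise, median -1.11, adjusted p = 1.09e-05). LMNB1, the lamin B1 gene, had 2 counts against 99 (ratio 40.3, interval 10.9 to 337). These 3 list calls held with an estimated correlation. Of 18 replication-dependent histone genes, 9 rose and 2 fell (10 and 2 list-wise, median 1.05, adjusted p = 0.0227, 0.051 with an estimated correlation), and without library T2, 10 rose and 4 fell. HIST1H4H rose by 3.29 (SE 0.35) and HIST1H4C fell by 5.67 (SE 0.72; 4.36 without control replicate 2), both genes of histone H4.

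Matrix, contractile, interferon-stimulated and ribosomal protein genes fell as well. Of 32 fibrillar collagen and matrix genes, 3 rose and 19 fell, also list-wise (median -2, adjusted p = 1.89e-05, 0.184 with an estimated correlation), and 5 rose without library T2. COL1A1, a chain of type I collagen (ENSG00000108821, GRCh38 chromosome 17, 50183289 to 50201632), fell from 11200 ± 2230 to 329 ± 31.8 CPM (log2 fold change -5.09, SE 0.41, adjusted p = 6.27e-09), and ELN, the elastin gene, fell by 6.56 (SE 0.57). Of 22 contractile and myofibroblast genes, 0 rose and 18 fell, also list-wise (median -1.62, and -1.43 with 1 member at its bound; adjusted p = 7.2e-10, 0.0768 with an estimated correlation); TAGLN, an actin-binding protein of contractile cells whose gene shares reads with another, fell by 4.09 (SE 0.36). Of 30 interferon-stimulated genes, 1 rose and 21 fell (1 and 22 list-wise, median -2.05, adjusted p = 1e-07, held with an estimated correlation). OAS3, an antiviral oligoadenylate synthetase gene, fell by 5.93 (SE 0.48). Of 57 cytosolic ribosomal protein genes, 0 rose and 45 fell (0 and 49 list-wise, median -1.09, adjusted p = 2.82e-11, 0.0641 with an estimated correlation).

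Several lists of stress and secretion genes had members moving both ways and were not called in BJ with bortezomib. Of 30 p53 target genes, 8 rose and 4 fell, also list-wise (median 0.00, mean -0.02, test direction up; adjusted p = 0.481), and without library T2, 10 rose and 8 fell. CDKN1A, the gene of the cell cycle inhibitor p21 (ENSG00000124762, GRCh38 chromosome 6, 36676460 to 36687339), rose from 503 ± 59.3 to 1110 ± 97.2 CPM (log2 fold change 1.15, SE 0.20, adjusted p = 0.000107), while CDKN2A, annotated as the gene of the inhibitor p16 and sharing reads with another gene, fell (-2.88, SE 0.63). Of 29 ATF4 target and amino acid response genes, 7 rose and 13 fell (8 and 13 list-wise, median -0.36, adjusted p = 0.148), with PSAT1, a serine synthesis enzyme gene, falling by 5.22 (SE 0.44). Of 21 inflammatory secreted factor genes, 7 rose and 4 fell (8 and 4 list-wise, median 0.80, and 0.64 with 2 members at their bound; adjusted p = 0.247). CXCL8, a neutrophil chemokine gene, rose by 5.96 (SE 1.15; 7.67 without control replicate 1), and CXCL12, a chemokine made by stromal cells, fell by 6.04 (SE 0.56). Of 33 secreted protease and growth factor genes, 10 rose and 9 fell (11 and 9 list-wise, median -0.14, mean 0.13; adjusted p = 0.773). The collagenase gene MMP1 rose from 73.5 ± 6.24 to 4410 ± 407 CPM (log2 fold change 5.90, SE 0.71, adjusted p = 1.3e-06), and IGFBP5, a growth factor binding protein gene, fell by 4.89 (SE 0.36). IL6, an inflammatory cytokine gene, had 46 counts over all libraries and was not tested.

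In BJ with bortezomib 6583 genes changed, of which 2981 were higher and 3602 lower; 1935 were at least 2-fold higher and 2959 at least 2-fold lower. With the replicates paired in a replicate block the count was 5769. Among genes that met the naming rule (a symbol, a mean of at least 10 CPM and separated groups), the largest rises included IL36B, a cytokine gene with 0 control counts (at least 90.5-fold higher, 21.9 ± 4.57 CPM in treated cells), CCL26, a chemokine gene with 438 counts against 1 (ratio 539, interval 96.2 to 21300), and PTPRN, a gene of neuroendocrine granules (1.32 ± 0.568 to 146 ± 19.4 CPM). LINC01705, a long noncoding RNA, had 970 counts against 3 (ratio 398, interval 136 to 1930), LINC00520, another, rose by 6.42 (SE 0.73), and C11orf96, which shares reads with AC087521.1, rose by 8.50 (SE 1.13). Under the same rule the largest falls, besides ELN and CXCL12, included EFHD1 (log2 fold change -6.36, SE 0.64) and the matrix gene MXRA5 (-6.04, SE 0.78). SERTAD4 had 3 counts against 438 (ratio 119, interval 40.4 to 578) and GRIA1, a glutamate receptor gene, 3 against 261 (ratio 70.8, interval 23.9 to 345). Leaving out 1 library moved EFHD1 to -7.87 (treated replicate 1), ELN to -7.67 and CXCL12 to -7.20 (treated replicate 2) and LINC00520 to 7.88 (control replicate 1).

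To find responses to oxidative stress in skin fibroblasts, H2O2-treated BJ cells were compared with their controls. Genes of division, replication, chromatin and interferon response fell, and p53 targets and polyadenylated histone RNA rose. Of 33 mitosis and G2/M genes, 0 rose and 26 fell (1 and 30 list-wise, median -1.87, adjusted p = 1.56e-21). MKI67 fell by 3.36 (SE 0.32, adjusted p = 3.51e-06). Of 36 DNA replication genes, 1 rose and 8 fell (1 and 13 list-wise, median -0.80, adjusted p = 2.34e-05), with RRM2 falling by 2.25 (SE 0.29), and 5 fell without library T2. Of 25 chromatin and nuclear envelope genes, 0 rose and 9 fell (1 and 14 list-wise, median -0.55, adjusted p = 2.34e-05), among them LMNB1 (-2.54, SE 0.51). Of 30 p53 target genes, 15 rose and 0 fell (19 and 0 list-wise, median 0.81, adjusted p = 3.81e-10). CDKN1A rose from 445 ± 16.7 to 2200 ± 769 CPM (log2 fold change 2.31, SE 0.21, adjusted p = 3.09e-06), MDM2, a ubiquitin ligase gene that restrains p53 and shares reads with another gene, by 1.3 (SE 0.19), and FDXR, a mitochondrial reductase gene, by 2.51 (SE 0.37), or by 1.61 without library T2. Of 18 histone genes, 6 rose and 1 fell (7 and 1 list-wise, median 0.91, adjusted p = 0.000152). Of 30 interferon-stimulated genes, 1 rose and 6 fell (1 and 13 list-wise, median -0.80, adjusted p = 5.14e-06). These 6 list calls held with an estimated correlation.

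Under the naming rule, the 6 largest rises in BJ with H2O2 were taken by name or shared reads as nuclear copies of mitochondrial sequence. No mitochondrial gene is in the tables, so reads of mitochondrial transcripts were not told apart from reads of these copies. They were MTRNR2L2 (log2 fold change 4.54, SE 0.68), MTND4P35 (4.35, SE 0.78), MIR4485, which shares reads with MTRNR2L8 (4.08, SE 0.50), MTND2P28 (4.01, SE 0.41), MTRNR2L12 (3.93, SE 0.54) and MTCO1P53 (3.74, SE 0.55). Without library T2 the values were 3.63, 3.67, 3.1, 3.12, 2.87 and 2.78, and all 6 stayed called. MTND2P28 stood at 391 ± 43.4 CPM in controls and 6300 ± 5160 CPM in treated cells, the highest level being that of replicate 2. The largest falls at a mean of at least 10 CPM were NUSAP1 (-3.25, SE 0.40), ANLN (-3.08, SE 0.47) and PRC1, which shares reads with AC068831.7 (-2.64, SE 0.44), all genes of spindle or cytokinesis proteins, and TINAGL1 (-2.81, SE 0.51), WNT2, a secreted signal (-2.57, SE 0.49), and A2M-AS1 (-2.56, SE 0.47). Without treated replicate 1 TINAGL1 stood at -3.43 and PRC1 at -3.53. GDF15, a stress-induced cytokine of the TGF-beta family, rose by 2.80 (SE 0.55, adjusted p = 0.00518; 2.19 without library T2), and IGFBP3, a growth factor binding protein gene, fell by 2.44 (SE 0.67, adjusted p = 0.0298; -2.46 to -2.40 and 0.0696 to 0.0891 without any 1 control). MMP3, the stromelysin gene, rose by 3.19 (SE 0.79, adjusted p = 0.0193), but was not called without library T2 (3.31, adjusted p = 0.0695) or any 1 control (2.95 to 3.46, adjusted p of 0.0707 to 0.0932). MMP1 (1.60, SE 0.59, adjusted p = 0.0852), COL1A1 (-0.60, adjusted p = 0.259) and HMOX1 (0.68, adjusted p = 0.192) were not called; HMOX1 was at -0.01 without library T2 (adjusted p = 0.993) and at 1 without treated replicate 1 (adjusted p = 0.0272).

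In BJ with H2O2 the called members, and for some lists the call, depended on library T2. Of 34 proteasome subunit genes, 12 rose and 0 fell (15 and 0 list-wise, median 0.30, adjusted p = 0.00149, 0.0549 with an estimated correlation), with PSMD2 at 0.74 (SE 0.17, not called without control replicate 1 or 2); without that library 2 rose, but the median was 0.29 and the list stayed called (adjusted p = 3.21e-08, range 1.35e-08 to 0.0549 over the alternatives). Of 57 cytosolic ribosomal protein genes, 6 rose and 0 fell, also list-wise (median 0.33, adjusted p = 0.011, 0.487 with an estimated correlation), with RPS19 at 1.35 (SE 0.34, not called without any 1 control); without that library RPS19 was at 0.49, 0 rose, the median was 0.05 and the list was not called (adjusted p = 0.201, range 0.011 to 0.487). Of 30 NRF2 target and antioxidant genes, 6 rose and 0 fell (6 and 2 list-wise, median 0.18, adjusted p = 0.219); without that library 2 rose. Matrix genes fell as a list (0 rose and 2 fell of 32, 0 and 3 list-wise, median -0.60, adjusted p = 2.34e-05, 0.19 with an estimated correlation); without that library 1 rose and 3 fell, and the list stayed called (median -0.39, adjusted p = 1.19e-06, range 1.19e-06 to 0.19). Lists that were not called, with or without that library, were heat shock proteins (median -0.10, test direction up, adjusted p = 0.805), ATF4 targets (0.30, adjusted p = 0.351), autophagy genes (0.00, adjusted p = 0.296), lysosome genes (0.13, adjusted p = 0.523), contractile genes (0.15, adjusted p = 0.351) and inflammatory factors (0.08, adjusted p = 0.621). Secreted proteases were not called either (2 rose, 1 fell, also list-wise, median 0.36, adjusted p = 0.294). Without that library they were called as higher (5 rose, 1 fell, median 0.52, adjusted p = 3.26e-05, range 3.26e-05 to 0.734), 1 of 5 list calls gained against 1 lost.

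In BJ with H2O2 1385 genes changed, 925 higher (66.8%) and 460 lower, with 706 and 338 at least 2-fold. The share of higher genes was 57.2% with library size in place of TMM and 42.1% with limma-trend, where 788 genes were called. Without library T2, 671 genes were called, 315 higher and 356 lower, and 502 of these were among the 1385; without treated replicate 1 or 3 the counts were 3962 and 2961, and without control replicate 1, 2 or 3 they were 366, 217 and 238. Of 140 named values in these cells, 36 lost the call without library T2 and 43, 54 and 50 without control replicate 1, 2 or 3. The count was 183 with a replicate block, 2702 with DESeq2 and 0 with only the 6 libraries of the comparison, where 0 of the named calls in these cells held.

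To find responses to proteasome inhibition in lung fibroblasts, bortezomib-treated HFL1 cells were compared with their controls. Genes of cell division, replication, chromatin and amino acid response fell, and genes of the proteasome, p53 response, antioxidant defence, autophagy and lysosomes rose. Of 33 mitosis and G2/M genes, 0 rose and 33 fell, also list-wise (median -5.47, adjusted p = 3.01e-41). AURKB, a mitotic kinase gene, fell by 7.11 (SE 0.34, adjusted p = 8.37e-12). Of 36 replication genes, 0 rose and 30 fell (0 and 32 list-wise, median -3.12, adjusted p = 1.19e-22), with RRM2 falling by 4.95 (SE 0.30). Of 25 chromatin and nuclear envelope genes, 0 rose and 21 fell (0 and 22 list-wise, median -1.82, adjusted p = 9.21e-16), among them LMNB1 (-5.53, SE 0.49). Of 29 ATF4 target and amino acid response genes, 0 rose and 20 fell (0 and 22 list-wise, median -1.47, adjusted p = 8.11e-12). ASNS, asparagine synthetase, sharing reads with AC079781.5, fell from 118 ± 9.52 to 3.57 ± 0.154 CPM (log2 fold change -5.04, SE 0.31, adjusted p = 1.46e-10). Against the line's H2O2-arm controls (ASNS 18.4 ± 1.03 CPM) the ATF4 list median was -0.32. Of 34 proteasome subunit genes, 28 rose and 0 fell (29 and 0 list-wise, median 1.35, adjusted p = 1.7e-16). These 5 list calls held with an estimated correlation.

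Stress-response genes rose in bortezomib-treated HFL1 cells. Of 30 p53 target genes, 10 rose and 0 fell (12 and 1 list-wise, median 0.70, adjusted p = 0.000124); CDKN1A rose from 320 ± 33 to 1400 ± 229 CPM (log2 fold change 2.13, SE 0.21, adjusted p = 9.1e-08) and MDM2 by 1.87 (SE 0.19). Of 30 NRF2 target and antioxidant genes, 18 rose and 1 fell, also list-wise (median 1.27, adjusted p = 3.69e-09). HMOX1 was not called (0.50, adjusted p = 0.3). Of 28 autophagy and ubiquitin adaptor genes, 14 rose and 0 fell (16 and 0 list-wise, median 0.69, adjusted p = 1.63e-06), with SQSTM1 rising from 371 ± 20.2 to 2220 ± 589 CPM. Of 32 lysosome genes, 9 rose and 1 fell, also list-wise (median 0.51, adjusted p = 0.000152). Of 18 histone genes, 8 rose and 2 fell (9 and 2 list-wise, median 1.24, adjusted p = 0.0068), with HIST1H4H rising by 4.49 (SE 0.40). These 5 list calls held with an estimated correlation. Of 31 heat shock genes, 8 rose and 1 fell (10 and 1 list-wise, median 0.44, adjusted p = 0.0069, 0.147 with an estimated correlation). Leaving out library T2 gave 20 rising and 2 falling p53 targets, 20 rising lysosome genes, and 19 rising and 2 falling heat shock genes.

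Matrix and contractile genes fell in bortezomib-treated HFL1 cells, and secreted factors moved both ways. Of 32 matrix genes, 1 rose and 26 fell (1 and 28 list-wise, median -1.58, adjusted p = 1.3e-11, 0.0511 with an estimated correlation). ELN fell from 154 ± 23.6 to 0.411 ± 0.398 CPM (log2 fold change -8.44, SE 0.63, adjusted p = 1.97e-09) and COL1A1 fell by 3.17 (SE 0.37). Of 22 contractile genes, 0 rose and 16 fell, also list-wise (median -1.14, adjusted p = 7.12e-08, 0.107 with an estimated correlation). Of 21 inflammatory factor genes, 10 rose and 2 fell (12 and 3 list-wise, median 2.06, adjusted p = 0.164). The chemokine gene CXCL1 rose to 96.7 ± 150 CPM (log2 fold change 6.72, SE 1.27), a level whose SD exceeded its mean; it was 3.51 without treated replicate 2 and was not called with only the 6 libraries of the comparison. Of 33 secreted protease and growth factor genes, 8 rose and 2 fell, also list-wise (median 0.21, adjusted p = 0.379). MMP3 rose by 4.80 (SE 0.85) to 806 ± 1210 CPM, and by 1.92 without treated replicate 2. Of 30 interferon-stimulated genes, 5 rose and 6 fell, also list-wise (median 0.19, mean -0.30, test direction down; adjusted p = 0.709); MX1, an antiviral GTPase gene, rose by 2.77 (SE 0.44) and OAS3 had 2 counts against 122 (ratio 50, interval 13.5 to 417). Of 57 ribosomal protein genes, 1 rose and 1 fell (0 and 0 list-wise, median -0.09, adjusted p = 0.807). Leaving out library T2 gave 4 falling inflammatory factors, 6 falling secreted proteases, 8 rising interferon-stimulated genes, 2 rising matrix genes, and 3 rising and 6 falling ribosomal protein genes.

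In HFL1 with bortezomib 4426 genes changed, 2102 higher and 2324 lower, with 1387 and 1821 at least 2-fold. At a mean of at least 10 CPM the largest rises were PPP2R2C, a phosphatase subunit gene with 0 control counts (at least 217-fold higher, 44.5 ± 5.52 CPM), DYSF, a membrane repair gene (722 counts against 1, ratio 882, interval 158 to 34900), KIF1A, a motor protein gene (784 against 2, ratio 479, interval 132 to 3960), CXCL1, GPX3, a secreted peroxidase gene (3.09 ± 0.811 to 267 ± 46.1 CPM), and the dynein gene DYNC1I1 (6.33, SE 0.49). At that level the largest falls, besides ELN, were in genes of division: UBE2C (-8.08, SE 0.52), MYBL2 (1 count against 420, ratio 344, interval 61.4 to 13600), MKI67 (3 against 1029, ratio 281, interval 95.9 to 1360), CEP55 (1 against 314, ratio 257, interval 45.8 to 10200) and CDCA5 (1 against 297, ratio 243, interval 43.3 to 9640). Without library T2 the count was 7026. With library size in place of TMM the median log2 fold change of all genes moved from -0.025 to -0.139.

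To find responses to oxidative stress in lung fibroblasts, H2O2-treated HFL1 cells were compared with their controls. Division, replication and chromatin genes fell, and p53 targets and polyadenylated histone RNA rose. Of 33 mitosis and G2/M genes, 0 rose and 31 fell (0 and 32 list-wise, median -3.43, adjusted p = 2.67e-74), with MKI67 falling by 3.99 (SE 0.30) and PLK1, a mitotic kinase gene that shares reads with ERN2, by 3.30 (SE 0.26). Of 36 replication genes, 0 rose and 18 fell (0 and 28 list-wise, median -1.34, adjusted p = 1.35e-23), with RRM2 falling by 3.40 (SE 0.29). Of 25 chromatin and nuclear envelope genes, 0 rose and 12 fell (0 and 18 list-wise, median -0.88, adjusted p = 1.84e-19), with LMNB1 falling by 3.06 (SE 0.42). Of 30 p53 target genes, 12 rose and 0 fell (18 and 0 list-wise, median 0.79, adjusted p = 1.56e-21); CDKN1A rose from 337 ± 16.8 to 1800 ± 120 CPM (log2 fold change 2.42, SE 0.21, adjusted p = 1.49e-07) and MDM2 by 1.71 (SE 0.19). Of 18 histone genes, 5 rose and 1 fell (11 and 1 list-wise, median 1.32, adjusted p = 3.58e-10). Of 29 ATF4 target genes, 2 rose and 0 fell (3 and 0 list-wise, median 0.41, adjusted p = 0.000755); they were SESN2, a stress-induced regulator of growth signalling (1.19, SE 0.22), and SLC7A11, a cystine transporter gene that shares reads with another gene (1.07, SE 0.22). With library T2 left out, 24 p53 targets and 11 histone genes rose, and 7 ATF4 targets rose and 2 fell. These 6 list calls held with an estimated correlation.

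Other lists were called in HFL1 with H2O2 with few or 0 called members, and lost the call with an estimated correlation. Secreted protease and growth factor genes rose as a list (4 rose, 0 fell; 7 and 0 list-wise, median 0.57, and 0.51 with 1 member at its bound; adjusted p = 3.18e-05, 0.147 with an estimated correlation). Its member MMP3 (5.06, SE 0.92) rose. Matrix genes fell as a list (0 rose, 3 fell; 0 and 9 list-wise, median -0.64, adjusted p = 2.87e-09, 0.0781 with an estimated correlation); COL1A1 was not called (-1.14, adjusted p = 0.0823; -1.47, adjusted p = 0.0364 without treated replicate 2). Interferon-stimulated genes fell as a list (0 rose, 4 fell; 0 and 6 list-wise, median -0.45, adjusted p = 0.00119, 0.099 with an estimated correlation), with OAS3 falling by 2.65 (SE 0.38). NRF2 targets rose as a list (3 rose, 0 fell; 4 and 0 list-wise, median 0.17, adjusted p = 0.00612, 0.0647 with an estimated correlation). Heat shock genes rose as a list (1 rose, 0 fell, also list-wise, median 0.22, adjusted p = 0.00297, 0.11 with an estimated correlation), and the riser was HSPA4L, which shares reads with another gene (1.64, SE 0.22). With 0 members called in either direction, proteasome genes (median 0.21, adjusted p = 0.00124, 0.0532 with an estimated correlation) and lysosome genes (median 0.23, adjusted p = 0.00577, 0.0961 with an estimated correlation) were called as higher. Ribosomal protein genes (median 0.12, adjusted p = 0.0263, 0.54 with an estimated correlation) were called as higher and contractile genes (median -0.34, adjusted p = 0.0143, 0.487 with an estimated correlation) as lower, again with 0 members called. These counts of 0 depended on 1 library of another group: without library T2, 6 proteasome, 5 lysosome and 1 ribosomal protein genes rose and 4 contractile genes fell. In that fit 8 secreted protease, 8 NRF2 target, 4 heat shock and 3 autophagy genes rose, 15 matrix genes fell, and of interferon-stimulated genes 1 rose and 7 fell. Autophagy genes (0 rose, 0 fell; median 0.06, adjusted p = 0.487) and inflammatory factors (0 rose, 2 fell, also list-wise, median 0.26, and 0.17 with 2 members at their bound, test direction down; adjusted p = 0.842) were not called; CXCL12 fell by 3.07 (SE 0.40), or 3.88 without treated replicate 2.

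In HFL1 with H2O2 538 genes changed, 158 higher and 380 lower, with 116 and 317 at least 2-fold. Under the naming rule the largest rises were MMP3, TFPI2, a protease inhibitor gene (4.03, SE 0.81), SLC16A6, a transporter gene (3.76, SE 0.61), SERPINB2, another protease inhibitor gene (3.30, SE 0.67), and the copies of mitochondrial sequence MTRNR2L8, which shares reads with MIR4485 (3.09, SE 0.47), and MTND4P35 (2.92, SE 0.72), whose reads were not told apart from those of mitochondrial transcripts. The largest falls under it were genes of the spindle, the kinetochore and mitotic control: NUF2 (-5.41, SE 0.58), CKAP2L (-4.89, SE 0.36), UBE2C (-4.76, SE 0.42), MKI67, CDK1 (-3.94, SE 0.48) and CENPF (-3.91, SE 0.32). GDF15 rose by 2.67 (SE 0.54). Without treated replicate 3 the values were 4.25 for MMP3, 2.92 for SLC16A6, -6.70 for NUF2, -5.60 for CKAP2L, -5.47 for UBE2C and -4.76 for CDK1, and TFPI2 was at 3.44 without treated replicate 2. MTND4P35 lost its call without any 1 of the 6 libraries except treated replicate 2 (2.70 to 3.03, adjusted p of 0.0612 to 0.133). The count was 308 and 281 without treated replicate 1 or 3, 318, 310 and 343 without control replicate 1, 2 or 3, and 1845 without library T2. With a replicate block it was 281, and with only the 6 libraries of the comparison 2175.

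**Figure D2:**
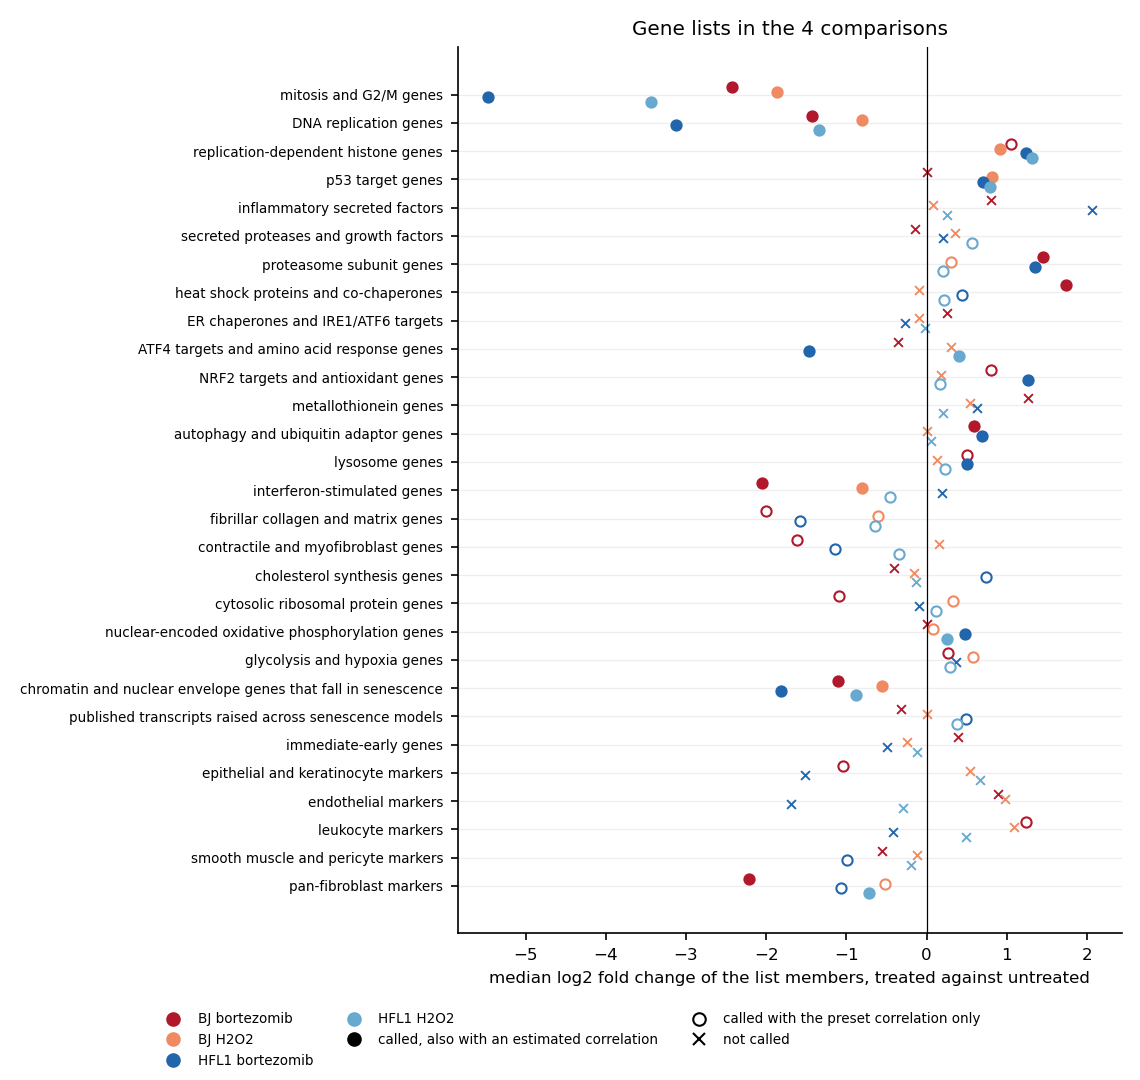
Median log2 fold change of the members of each gene list (horizontal axis) in the 4 comparisons; colours are comparisons, filled points are lists called with both the preset and the estimated correlation, open points those called with the preset correlation only, and crosses lists not called. Mitosis genes had medians of -2.42, -1.87, -5.47 and -3.43, and proteasome genes were at 1.45 and 1.35 with bortezomib.

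To find genes shared by both inducers and both lines, the 4 comparisons were intersected. All 4 comparisons shared 146 genes, 18 rising and 128 falling, where independent lists would share 0.22 and 0.35. CDKN1A, GDF15, MMP3, HIST1H4H, HIST1H1C, CD68 (which encodes a lysosomal membrane protein and shares reads with AC016876.1), NIPAL3, GSTO1, a glutathione transferase gene, and the histone genes HIST2H2AA3 and HIST2H2AA4, which share reads with each other, were the 10 strongest shared rises among genes with a symbol and a mean of at least 10 CPM. The 10 strongest shared falls under these limits were MKI67, ANLN, UBE2C, HJURP, PRC1, SHCBP1, KNL1, CXCL12, CDK1 and RRM2, of which all but CXCL12 encode proteins of division or nucleotide supply or, for SHCBP1, a protein of cytokinesis. SHCBP1 and CDK1 had 0 counts in bortezomib-treated BJ cells, at least 27.7-fold and 28.3-fold lower. In Fisher's exact tests over 58 list and direction pairs, shared falls held 22 of 33 mitosis genes (0.26 expected, adjusted p = 9.28e-38), 7 of 25 chromatin genes (adjusted p = 2.05e-08) and 5 replication genes (adjusted p = 0.000129). Shared rises held 3 genes of the p53 target list (adjusted p = 8.94e-05) and 2 of the histone list (adjusted p = 0.00206), which lacks HIST2H2AA3 and HIST2H2AA4. Of the 18 shared rises, 8 share reads with another gene. Some of these calls were lost without 1 library. MMP3 was not called in BJ with H2O2 without library T2 or any 1 control, as given above. GDF15 was called in HFL1 with bortezomib at 1.49 (SE 0.53, adjusted p = 0.0385), but stood at 0.09 without treated replicate 2 of that group (adjusted p = 0.915), which had 309.6 CPM against 63.57 and 39.97 in the others; without any 1 control it was at 1.40 to 1.63 (adjusted p of 0.0696 to 0.115). In HFL1 with H2O2 the call of CD68 was lost without treated replicate 1 or 3 or control replicate 1 or 2 (1.13 to 1.28, adjusted p of 0.0528 to 0.0935), and those of HIST2H2AA3 and HIST2H2AA4 without treated replicate 3 or control replicate 1 or 2 (1.54 to 1.65, adjusted p of 0.0528 to 0.0605). GSTO1 lost a call without treated replicate 3 or control replicate 1 of that comparison (0.75 and 0.90, adjusted p = 0.0879 and 0.0537) and without control replicate 2 or 3 of BJ with H2O2 (0.96 and 0.94, adjusted p = 0.0527 and 0.0528), and CDK1 without the latter control (-1.97, adjusted p = 0.0742). The count was 58 with a replicate block, 0 with only the libraries of each comparison, 93, 80 and 90 without a control of the BJ H2O2 arm (replicate 1, 2 or 3) and 241 without library T2.

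The responses were also compared in pairs. The bortezomib responses of BJ and HFL1 shared 1189 rises and 1309 falls (387.75 and 518.01 expected), with 175 genes in opposite directions and a Pearson r of 0.551 across genes (Spearman 0.517). The H2O2 responses of both lines shared 80 rises and 172 falls (9.04 and 10.82 expected) with 0 opposite (r = 0.485, Spearman 0.445). Within BJ the inducers shared 264 rises and 312 falls (170.63 and 102.53 expected) with 129 opposite (r = 0.278, Spearman 0.225), and within HFL1 77 and 312 (20.55 and 54.65 expected) with 10 opposite (r = 0.444, Spearman 0.364). Across line and inducer, BJ with bortezomib and HFL1 with H2O2 shared 61 rises and 251 falls (29.15 and 84.7 expected; 44 opposite; r = 0.306, Spearman 0.244), and BJ with H2O2 and HFL1 with bortezomib 241 and 251 (120.32 and 66.15 expected; 47 opposite; r = 0.275, Spearman 0.219). These 6 correlations are across genes, which are not independent replicates.

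Bortezomib effects were compared between lines (HFL1 minus BJ). Mitosis, replication, heat shock and ATF4 target genes responded more negatively in HFL1, and interferon-stimulated, cholesterol synthesis and p53 target genes more positively. Of 33 mitosis genes, 0 were higher and 21 lower (median -2.75, adjusted p = 2.35e-23), with AURKB at -5.50 (SE 0.47). Heat shock genes (0 higher, 16 lower of 31; median -1.14, adjusted p = 2.39e-12), ATF4 targets (0 and 14 of 29; median -1.35, adjusted p = 8.94e-07) and replication genes (0 and 11 of 36; median -1.23, adjusted p = 1.21e-08) were lower. Interferon-stimulated genes (11 higher, 1 lower of 30; median 1.64, adjusted p = 6.11e-09), cholesterol synthesis genes (10 and 0 of 24; median 1.07, adjusted p = 1.33e-05) and p53 targets (9 and 1 of 30; median 0.79, adjusted p = 0.0109) were higher. These 7 calls held with an estimated correlation. Control level was not separated from drug effect (untreated AURKB 84.2 CPM in HFL1, 10.7 in BJ). The untreated HFL1 cells of the bortezomib arm, which enter these differences, themselves lay above those of the H2O2 arm in mitosis (median 1.25), ATF4 target (1.05), replication (0.85, adjusted p = 2.7e-13) and heat shock genes (0.27, adjusted p = 0.00289, 0.169 with an estimated correlation). They lay below them in cholesterol synthesis genes (-0.59), p53 targets (-0.26, adjusted p = 0.00603) and interferon-stimulated genes (-0.43, adjusted p = 0.00623, 0.229 with an estimated correlation), and in BJ the controls of the bortezomib arm lay above those of the H2O2 arm in interferon-stimulated genes (0.36, adjusted p = 1.94e-06). Of 57 ribosomal protein genes, 19 were higher and 0 lower (median 1, adjusted p = 9.6e-13, 0.0748 with an estimated correlation). In all, 2180 genes differed, 1171 higher and 1009 lower; with library size in place of TMM 1019 were higher and 1338 lower, the median of all genes moving from 0.055 to -0.080. The count was 1399 with a replicate block, 3893 with only the 12 libraries and 4918 without library T2.

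For H2O2 the lines differed in 1 gene, CKAP2L, a gene of the mitotic spindle (HFL1 minus BJ -3.18, SE 0.46, adjusted p = 0.0108), and 1298 genes had an unadjusted p below 0.05. CKAP2L fell by 4.89 in HFL1 and by 1.72 in BJ; its difference was not called without HFL1 treated replicate 1, without BJ control replicate 1 or 3, with a replicate block, or with only the 12 libraries of the contrast. Mitosis genes as a list fell further in HFL1 (median difference -1.22, adjusted p = 9.93e-16), as did replication genes (-0.61, adjusted p = 1.83e-05), each with 0 members called, and both calls held with an estimated correlation. The count was 27 with DESeq2 and 44 with no filter on low counts.

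To compare the inducers within a line, the H2O2 effect was subtracted from the bortezomib effect. In BJ, proteasome genes (19 higher, 0 lower of 34; median difference 1.16, adjusted p = 1.09e-10) and heat shock genes (22 and 1 of 31; median 1.76, adjusted p = 1.51e-12) responded more to bortezomib, and p53 targets (0 and 12 of 30; median -0.74, adjusted p = 0.00603) more to H2O2; these calls held with an estimated correlation. Ribosomal protein genes were lower with bortezomib (0 and 42 of 57; median -1.38, adjusted p = 2.5e-13, 0.0662 with an estimated correlation). At a mean of at least 10 CPM the largest differences were MIR6843, which shares reads with CLU (7.63, SE 0.59), C11orf96 (7.32, SE 1.89; 7.44, adjusted p = 0.113 without library T2), PTPRN (6.84, SE 0.79), HSPA1A (6.69, SE 0.79) and LINC01705 (6.20, SE 0.90). In the other direction they were CLDN11, a tight junction gene, SYT1, a vesicle protein gene, EDN1, the endothelin gene (-5.94, SE 0.78), KRT17, a keratin gene (-5.92, SE 0.90), and ELN (-5.51, SE 0.71). CLDN11 had 2 counts against 171 with bortezomib (ratio 69.5, interval 19 to 579) and SYT1 1 against 238 (ratio 194, interval 34.4 to 7680). In all, 4295 genes differed, 1740 higher and 2555 lower; with library size in place of TMM the median of all genes moved from -0.103 to 0.026. The count was 2307 with only the 12 libraries of the contrast.

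In HFL1, proteasome genes (13 higher, 0 lower of 34; median difference 1.03, adjusted p = 1.72e-14) responded more positively to bortezomib, and ATF4 targets (0 and 17 of 29; median -1.86, adjusted p = 1.23e-21) more negatively; both calls held with an estimated correlation, and ATF4 targets were already 1.05 higher (median) in the controls of the bortezomib arm. At a mean of at least 10 CPM the largest differences were PPP2R2C (0 counts in bortezomib-arm controls), PDK4, a kinase gene of glucose oxidation (7.32, SE 1.83), GPX3 (6.54, SE 0.59), FBXO2 (5.25, SE 0.65) and B4GALNT1 (4.71, SE 0.51). On the other side stood ELN (-6.96, SE 0.96), NPTX1 (-6.26, SE 0.69), ASNS (-5.50, SE 0.39), PCK2 (-4.97, SE 0.57) and COL5A3 (-4.88, SE 0.58). PPP2R2C was not called with a replicate block (adjusted p = 0.142) or without replicate 1 of the H2O2-arm controls (adjusted p = 1). PDK4 was not called without that library (7.16, adjusted p = 0.0544), with limma-trend, with only the 12 libraries of the contrast or without both libraries that stood apart (adjusted p = 0.132, 0.187 and 0.0743). In all, 1241 genes differed, 603 higher and 638 lower; the count was 644 with a replicate block, 827 and 808 without control replicate 1 of the bortezomib or the H2O2 arm, and 3507 without library T2.

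The control groups of a line were compared to see how far untreated cells differed between arms. In BJ 0 genes differed in edgeR and 0 in DESeq2, and 265 had an unadjusted p below 0.05. As a list, interferon-stimulated genes were higher in the bortezomib arm (median 0.36, adjusted p = 1.94e-06, 0.0339 with an estimated correlation). In HFL1 602 genes differed, 345 higher and 257 lower in the bortezomib arm. Mitosis genes (20 higher, 0 lower of 33; median 1.25, adjusted p = 2.16e-24) and ATF4 targets (15 and 0 of 29; median 1.05, adjusted p = 2.16e-24) were higher there and cholesterol synthesis genes lower (0 and 4 of 24; median -0.59, adjusted p = 5.64e-07), and these calls held with an estimated correlation. The HFL1 count was 206, 244, 193, 191, 189 and 220 without 1 of its own 6 libraries, 4304 with those 6 alone, and 2310 without library T2.

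**Figure D3:**
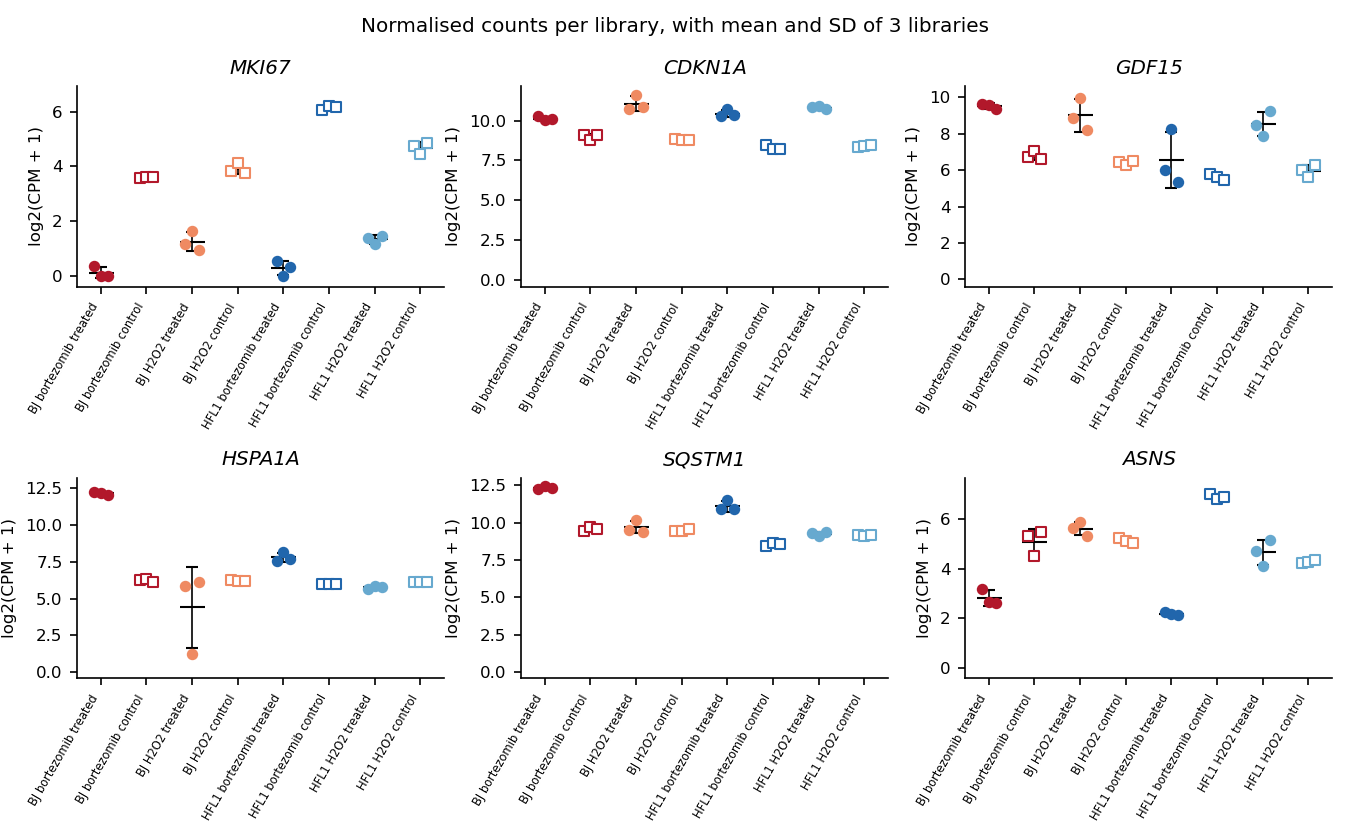
Levels of 6 genes as log2(CPM + 1) in each library (points) of the 8 groups, with the mean and SD of 3 libraries; filled circles are treated and open squares untreated. CDKN1A lies higher in all 4 treated groups than in their controls.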

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

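The tests for a wrong label and for a few dominant genes in the library that stood apart, for GC content and for a raised control level in the untreated HFL1 groups, and for scaling in the ribosomal protein genes were chosen only after the results were seen, as were the splits of the libraries for every count except that of genes shared by all 4 comparisons.

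Effects that differed between the lines, by a test of the difference itself (HFL1 minus BJ), were singled out. With bortezomib 2180 genes differed. In 100 splits the real grouping gave 2180 and the highest other split 1894, so 1 split, the real one, reached that count, and the high count of another split points to a structure of the samples. With H2O2 1 gene differed, CKAP2L (-3.18), and the highest other of 100 splits gave 0. These splits mix lines and treatments, which raises the spread, so they do not isolate a difference of effects and leave chance open. The H2O2 count was 0 to 9 on leaving out 1 library.

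At a mean of at least 10 CPM the genes with the largest differences under bortezomib were VWA5A (10.07), RGCC (7.84), CAVIN2 (6.74), GPC6 (6.42) and PRELP (5.90) on the positive side. On the negative side they were LINC01705 (-7.62), ADM2 (-6.58), AURKB (-5.50), LINC00520 (-4.97) and ITGB3 (-4.80). Fitted values of genes with 0 to 3 counts in a group depend on the prior count and are no bound. VWA5A, RGCC and GPC6 had 0 counts in bortezomib-treated BJ cells, at least 31-fold, 56.1-fold and 39.5-fold lower than their controls, and CAVIN2 had 1 count against 68 (ratio 55.3, interval 9.6 to 2220). ADM2 had 0 counts in bortezomib-treated HFL1 cells, at least 67-fold lower, and LINC01705 had 3 counts in untreated BJ cells. The call of RGCC was lost without BJ treated replicate 1, 2 or 3, BJ control replicate 1 or 2, HFL1 treated replicate 1 or HFL1 control replicate 1 or 3 (5.44 to 7.95, adjusted p of 0.055 to 0.151). It was also lost with library size in place of TMM, with only the 12 libraries, a replicate block or limma-trend, and without the libraries that stood apart (adjusted p of 0.0523 to 0.178). LINC00520 lost its call without HFL1 control replicate 2 (-4.13, adjusted p = 0.0775) and GPC6 with limma-trend (adjusted p = 0.0579).

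In the fixed panel the differences under bortezomib included 0.98 for CDKN1A, -2.09 for CCNB1, -3.21 for MMP1, -3.34 for HMOX1, -4.09 for HSPA1A, 1.93 for COL1A1 and 4.13 for CCN2. List medians of the difference were -2.75 for mitosis, -1.23 for replication, 0.79 for p53 target, -1.14 for heat shock, -1.35 for ATF4 target, 1.64 for interferon-stimulated and 1.07 for cholesterol synthesis genes. With H2O2 they were -1.22 for mitosis and -0.61 for replication genes. These list tests were chosen after the data were seen.

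Library T2 correlated at 0.770 with the farther of its group members. With an offset for GC content that value was 0.786, against 0.948 as the lowest within any other group, so GC content does not account for the whole distance. Mitosis genes had a mean log2 CPM of 0.99 there, 1.99 and 1.54 in its group members, and 3.30 to 3.37 in untreated BJ. A wrong label stays open, since that library had the fewest genes at 5 counts or more (14176). It correlated at 0.781 with its group members' mean and 0.755 at most with another group's. Its 10 most abundant genes held 9.75% of the counts, within the 7.47% to 19.51% of the other libraries, which argues against a few dominant genes. RNA quality or a different culture state stay open, and no biological explanation was tested.

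The untreated HFL1 groups of the 2 arms differed in 602 genes, with mitosis genes and ATF4 targets higher in the bortezomib arm. With an offset for GC content 772 genes were called, and with every library thinned to the smallest total 420, so neither GC content nor depth accounts for the whole difference. Against the untreated cells of the H2O2 arm, bortezomib-treated HFL1 cells had a median of -0.32 over the ATF4 list (3 higher, 9 lower), in place of -1.47 against their own controls, whereas mitosis genes still fell (median -4.12, 32 lower, 0 higher). How much of the fall of ATF4 targets rests on a raised level in the bortezomib-arm controls cannot be told apart from an effect of the drug, because each arm has its own controls. A difference in culture conditions or growth between the untreated cultures may underlie it and was not tested.

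Ribosomal protein genes fell with bortezomib in BJ (median -1.09) and 45 of 57 were called, while the median in HFL1 was -0.09. The scaling does not account for it, since the BJ median was -1.07 with either other scaling. Other genes matched on GC content and level (569 genes) had a median of -0.03, and the 42 members that share few reads a median of -1.09 with 32 called lower, which argues against GC content, abundance and reads shared with pseudogenes. A response of these genes that differs between the lines may account for the pattern, as a hypothesis found and tested on the same data. The list test of the difference was lost with an estimated correlation (adjusted p = 0.0748), and treatment lasted 10 days in BJ and 9 in HFL1.

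For the 4 comparisons and both pairs of untreated groups, the 10 splits of 6 libraries are too few for a share under 0.05. The real and highest other counts were 6583 and 2 for BJ with bortezomib, 1385 and 0 for BJ with H2O2, 4426 and 0 for HFL1 with bortezomib, 538 and 0 for HFL1 with H2O2, 602 and 0 for the untreated HFL1 groups, and 0 and 0 for the untreated BJ groups, where 10 of 10 splits gave as many. In 100 splits each, the inducers within BJ gave 4295 (highest other 2427, which points to a structure of the samples) and the inducers within HFL1 1241 (highest other 39). For the genes shared by all 4 comparisons, split within each comparison, 100 splits gave 146 and 0 as the highest other. Those splits mix treatments or arms and leave chance open in the same way, and wrong splits of 1 comparison called at most 2 genes, which left almost none to share.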

How the results depend on the processing

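Limma-trend, the GC offset, the restriction to genes that share few reads, the fits without the libraries that stood apart, and the alternatives for the correlations and for the untreated groups beyond those fixed beforehand were chosen only after the data were seen. The simulation changed fewer genes than each comparison called, so its recovery (22% to 34% at 2-fold) does not carry over. Small changes and genes near the floor could be missed. Of 9945 values of named genes under the alternatives, 9037 kept their direction and their side of the threshold, 654 lost the call, 254 gained it and 0 reversed. Where the cause is not named, the cause was not tested. The counts for BJ with bortezomib (5422 to 8887 without 1 library) stayed within 1.5 times under every alternative run.

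With only the libraries of a comparison, the fits had fewer libraries to estimate the spread. They called 0 genes for BJ with H2O2, 2175 for HFL1 with H2O2, 3893 for bortezomib by line, 0 for H2O2 by line, 2307 for the inducers within BJ, 3012 for the inducers within HFL1, 8 and 4304 for the untreated BJ and HFL1 groups, and 0 shared by all 4 comparisons. The replicate block gave 183 for BJ with H2O2, 281 for HFL1 with H2O2, 1399 for bortezomib by line, 0 for H2O2 by line, 644 for the inducers within HFL1 and 58 shared. In BJ with bortezomib, where pairing by number was uncertain, it gave 5769 genes. There it ended 1 of the calls among 137 named values (NDUFV2, adjusted p = 0.0582) and changed no list call. DESeq2 gave 2702 for BJ with H2O2, 27 for H2O2 by line, 1007 for the untreated HFL1 groups and 225 shared, and limma-trend gave 788 for BJ with H2O2. Without both libraries that stood apart the counts were 756 for BJ with H2O2, 7188 for HFL1 with bortezomib, 2058 for HFL1 with H2O2, 4642 for bortezomib by line, 10 for H2O2 by line, 3779 for the inducers within HFL1, 2515 for the untreated HFL1 groups and 262 shared. For H2O2 by line, RLE, the GC offset and genes sharing few reads each gave 2 genes, and no filter on low counts 44; no filter gave 6 for the untreated BJ groups.

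Leaving out 1 library gave 217 to 3962 genes for BJ with H2O2, 3348 to 7026 for HFL1 with bortezomib, 281 to 1845 for HFL1 with H2O2, 1591 to 4918 for bortezomib by line, 0 to 9 for H2O2 by line, 808 to 3507 for the inducers within HFL1, 0 to 1 and 189 to 2310 for the untreated BJ and HFL1 groups, and 80 to 241 shared. For HFL1 with either inducer, bortezomib by line and the inducers within HFL1 the highest values came without library T2. So did those for the untreated HFL1 groups and the shared genes.

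With no filter on low counts the correlations of fold changes fell to 0.124 (both inducers in BJ), 0.194 (bortezomib in both lines), 0.131 (BJ with bortezomib, HFL1 with H2O2), 0.004 (BJ with H2O2, HFL1 with bortezomib), 0.191 (H2O2 in both lines) and 0.022 (both inducers in HFL1); 41297 genes then entered, many with few counts. With a mean of at least 10 CPM they were 0.599 for bortezomib and 0.547 for H2O2 in both lines. Of the list calls, 8, 6, 11 and 8 held with an estimated correlation in BJ with bortezomib, BJ with H2O2, HFL1 with bortezomib and HFL1 with H2O2, out of 17, 12, 18 and 19, and 0 reversed under any setting with a direction.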

Other observations

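The values in this part come from lists fixed before the data were examined. The fits without library T2 were chosen only after the results were seen.

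Genes of energy and lipid metabolism moved in some comparisons. Of 24 cholesterol synthesis genes, 10 rose and 1 fell in HFL1 with bortezomib (11 and 1 list-wise, median 0.74, adjusted p = 0.000959, 0.0647 with an estimated correlation). MSMO1, a sterol oxidase gene, rose by 1.47 (SE 0.26). In BJ with bortezomib 3 rose and 6 fell, also list-wise (median -0.41, adjusted p = 0.161). With H2O2 2 rose and 2 fell in BJ (3 and 4 list-wise, median -0.16, adjusted p = 0.46) and 0 rose and 0 fell in HFL1 (1 and 1 list-wise, median -0.13, adjusted p = 0.281). Of 43 nuclear-encoded oxidative phosphorylation genes, 11 rose and 0 fell in HFL1 with bortezomib (19 and 0 list-wise, median 0.48, adjusted p = 0.000236). In HFL1 with H2O2 0 rose and 0 fell, also list-wise, but the list was called as higher (median 0.26, adjusted p = 0.000253); both HFL1 calls held with an estimated correlation. In BJ with H2O2 11 rose and 0 fell (18 and 0 list-wise, median 0.08, adjusted p = 0.0479, 0.234 with an estimated correlation), and without library T2, 1 rose, yet the list call was stronger (median 0.22, adjusted p = 1.13e-07, range 6.54e-08 to 0.234 over the alternatives). In BJ with bortezomib 2 rose and 4 fell (0 and 0 list-wise, median 0.01, mean -0.09, adjusted p = 0.682). Leaving out library T2 gave 15 rising and 10 falling oxidative phosphorylation genes in BJ with bortezomib, 27 rising in HFL1 with bortezomib and 8 in HFL1 with H2O2. For cholesterol synthesis genes it gave 12 falling in BJ with bortezomib, 16 rising in HFL1 with bortezomib, 2 rising and 4 falling in HFL1 with H2O2, and in BJ with H2O2 0 rising and 1 falling with a list call as lower (median -0.08, adjusted p = 0.044, range 0.0325 to 0.683).

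Of 23 glycolysis and hypoxia genes, 6 rose and 1 fell in BJ with bortezomib, also list-wise (median 0.27, adjusted p = 0.0436, 0.181 with an estimated correlation). In BJ with H2O2 9 rose and 1 fell (13 and 2 list-wise, median 0.58, adjusted p = 0.0155, 0.11 with an estimated correlation), and without library T2, 0 rose and 0 fell, the median was 0.17 and the list stayed called (adjusted p = 0.0131, range 0.00514 to 0.11). In HFL1 with bortezomib 7 rose and 1 fell (10 and 2 list-wise, median 0.37, adjusted p = 0.0536), with NDRG1, a hypoxia-induced gene, rising by 2.26 (SE 0.28), and in HFL1 with H2O2 1 rose and 0 fell, also list-wise (median 0.29, adjusted p = 0.00206, 0.0549 with an estimated correlation). Of 25 ER chaperone and IRE1/ATF6 target genes, 7 rose and 2 fell in BJ with bortezomib, also list-wise (median 0.25, adjusted p = 0.162), with HSPA5, the main ER chaperone gene, rising by 1.85 (SE 0.21). In BJ with H2O2 2 rose and 0 fell (4 and 0 list-wise, median -0.09, mean 0.04, adjusted p = 0.922), whereas without library T2 the list was called as higher with 1 rising (median 0.25, adjusted p = 0.000371, range 0.000371 to 0.96). It was not called in HFL1 with bortezomib (median -0.27, adjusted p = 0.579) or H2O2 (median -0.02, adjusted p = 0.887). Of 3 metallothionein genes tested, 2 rose and 0 fell in BJ with bortezomib (median 1.26, adjusted p = 0.182), with MT2A, a metal-binding protein gene that shares reads with another gene, rising by 2.43 (SE 0.39). The list was not called in BJ with H2O2, HFL1 with bortezomib or HFL1 with H2O2 either (medians 0.54, 0.63 and 0.20, adjusted p = 0.709, 0.807 and 0.294). The fit without library T2 gave 11 rising and 2 falling glycolysis genes in BJ with bortezomib, 10 and 6 in HFL1 with bortezomib (list called, adjusted p = 0.0345, range 0.0345 to 0.195) and 8 and 0 in HFL1 with H2O2. For ER genes it gave 12 and 5 in BJ with bortezomib.

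Of 34 published transcripts raised across senescence models, 13 rose and 0 fell in HFL1 with bortezomib (14 and 0 list-wise, median 0.49, adjusted p = 0.000865, 0.0927 with an estimated correlation), with TNFSF13B, a B-cell survival factor gene, rising by 3.46 (SE 0.50), or 2.71 without treated replicate 2. In HFL1 with H2O2 4 rose and 0 fell, also list-wise (median 0.38, adjusted p = 0.000483, 0.0781 with an estimated correlation), with CCND3, a cyclin gene, rising by 0.97 (SE 0.21; adjusted p = 0.0502 without control replicate 3). In BJ with bortezomib 10 rose and 7 fell, also list-wise (median -0.32, mean -0.30, test direction up, adjusted p = 0.684), and in BJ with H2O2 4 rose and 1 fell (5 and 2 list-wise, median 0.01, adjusted p = 0.829), but in the latter the list was called as higher without library T2 (4 rose, 0 fell, median 0.24, adjusted p = 0.0185, range 0.0185 to 0.928). Of 20 immediate-early genes, 6 rose and 4 fell in BJ with bortezomib (6 and 5 list-wise, median 0.39, mean -0.37, adjusted p = 0.554), with EGR1, a transcription factor gene, falling (-5.27, SE 0.64). The list was not called in BJ with H2O2, HFL1 with bortezomib or HFL1 with H2O2 (medians -0.25, -0.49 and -0.12, adjusted p = 0.481, 0.281 and 0.686). Leaving out library T2 gave 20 rising and 2 falling published transcripts in HFL1 with bortezomib and 10 rising in HFL1 with H2O2.

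Of 12 pan-fibroblast markers, 0 rose and 10 fell in BJ with bortezomib, also list-wise (median -2.21, adjusted p = 2.01e-05), and 0 rose and 1 fell in HFL1 with H2O2 (0 and 7 list-wise, median -0.72, adjusted p = 4.16e-06); both calls held with an estimated correlation. In HFL1 with bortezomib 1 rose and 8 fell (1 and 9 list-wise, median -1.07, adjusted p = 0.00102, 0.099 with an estimated correlation), and in BJ with H2O2 0 rose and 2 fell, also list-wise (median -0.52, adjusted p = 0.0372, 0.29 with an estimated correlation). The collagen genes among them also belong to the matrix list. Of 7 epithelial and keratinocyte markers tested, 1 rose and 6 fell in BJ with bortezomib, also list-wise (median -1.04, adjusted p = 0.0382, 0.139 with an estimated correlation), with the keratin gene KRT19 falling (-3.59, SE 0.55). That list was not called in BJ with H2O2, HFL1 with bortezomib or HFL1 with H2O2 (adjusted p = 0.226, 0.226 and 0.0796). The fit without library T2 gave 7 falling pan-fibroblast markers in HFL1 with H2O2 and 1 rising in BJ with bortezomib.

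Of 5 leukocyte markers tested, 2 rose and 0 fell in BJ with bortezomib, also list-wise (median 1.24, adjusted p = 0.0479, 0.0953 with an estimated correlation). They were CD68 (3.33, SE 0.28), and LAPTM5, a lysosomal protein gene of blood cells (2.23, SE 0.67; adjusted p = 0.0524 without control replicate 3), and each shares nearly all its reads with an overlapping gene. CD68 and LAPTM5 were also the 2 that rose in BJ with H2O2 (0 fell, also list-wise, median 1.09, adjusted p = 0.0623). Without library T2, 1 rose there and the list was called (median 0.52, adjusted p = 0.00748, range 0.0054 to 0.161), and the call in BJ with bortezomib was lost (adjusted p = 0.057, range 0.0345 to 0.0953). The list was not called in HFL1 with bortezomib (adjusted p = 0.951) or H2O2 (adjusted p = 0.141). The 4 endothelial markers tested were not called as a list in any comparison (adjusted p of 0.615 to 0.922). Of 12 smooth muscle and pericyte markers, 0 rose and 6 fell in HFL1 with bortezomib (1 and 6 list-wise, median -0.99, adjusted p = 0.0195, 0.159 with an estimated correlation). That list was not called in BJ with bortezomib, BJ with H2O2 or HFL1 with H2O2 (medians -0.55, -0.12 and -0.20, adjusted p = 0.341, 0.987 and 0.162). A fit that left out library T2 gave 2 rising smooth muscle markers in HFL1 with bortezomib.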
